A study of Homo sapiens with 5 samples.

How the data were processed

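MicroRNA levels were measured with 1-colour Illumina bead arrays, hybridised with Cy3-labelled total RNA, in the human ovarian carcinoma line SKOV3 and in 4 sublines derived from it that resist paclitaxel, a taxane that stabilises microtubules. The sublines carry the numbers 41, 43, 44 and 46 in the labels and are called sublines 1 to 4 here, in that order. The labels call them different sublines and do not say whether each was selected on its own, so the spread between them holds both their own differences, as far as they are independent, and the noise of the arrays. The parental line has a single array with no replicate. The sublines were read on version 2 of the microRNA panel and the parental line on version 1, so panel and group cannot be told apart in any comparison between them.

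The non-normalized table holds, per the file headers, a linear bead-summary intensity and a detection p-value for each probe and array. It was exported with BeadStudio 3.1.3 per the submitters' processing notes. A further deposited table of the parental array gives the intensity, the standard error over beads, a detection p-value rounded to 2 decimals and, in the category other, the number of beads behind each probe, all per the file headers. Comment lines in that deposited table say that identifiers of version 1 probes were not at hand and that the panels were merged by the gene name Illumina gives. The authors' value table holds log2 values of 338 probes. Its normalization is not given in the sources used here, but the 5 deposited log2 columns have nearly equal distributions, with medians of 9.17, 9.14, 9.17 and 9.16 for sublines 1 to 4 and 9.17 for the parental line. Within each array these log2 values kept the rank order of the deposited intensities (Spearman rho of 1 for each array), which settles their direction, while their filter and any centring stay unknown. All 338 probes had a detection p-value under 0.05 on at least 2 arrays, against 368 such probes among the shared ones.

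The version 2 table lists 1145 probes, of which 556 carry a parental value. Each of those 556 parental intensities also occurs among the 739 rows of the version 1 table, whereas 589 probes had subline values alone. The files used here do not pair version 2 probes with names. A name was therefore taken from the version 1 table where exactly 1 of its rows held the parental intensity of a probe. This named 301 probes, 223 of them microRNAs and 78 other predicted small RNAs, and left 255 without a name. The detection p-value of the named row equalled that of the probe, to within rounding at 2 decimals, for 301 of 301. Within an array the detection p-value follows from the intensity, so this match was bound to hold and adds no support to the names. The pairing itself rests on the authors' merge, and the version 2 probe sequences were not used here. MicroRNA names and mature sequences are those of the version 1 annotation, without the species prefix, and can be old. Positions in that annotation come with no genome build, so the chromosome alone is given.

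Background was corrected within each array with limma's normexp model, its background level estimated from the detection p-values (R 4.3.3, limma 3.58.1). Each array was then scaled on its own so that its 75th percentile over the 285 probes detected on all 5 arrays was equal, an offset of 16 was added and log2 was taken. A difference is the log2 level of a subline minus the parental log2 level, given as the mean ± SD over 4 sublines, and the offset makes differences of dim probes smaller than they were. A probe was detected at a detection p-value under 0.05. Probes detected in the parental line or in every subline were compared, and a probe met the 2-fold rule when it lay at least 1 away from the parental level on the log2 scale, in the same direction, in every subline. Where no array of a group detected a probe, its fold is a bound: the mean of the other group against the mean of, per array, the higher of the lowest level among detected probes and the probe's own level. Such a bound holds for the mean of the sublines and for the setting it was computed in. Both groups' measured means stand beside each bound in the underlying tables.

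The plan made before the data were examined foresaw a limma test on quantile-normalized values if arrays of both groups shared a panel, and no test if the parental array stood alone on its panel. The second case applied. The plan also ruled out normalizing arrays of different panels together, and for this case it foresaw values side by side, as ranks or detection within each array. The log2 differences between the panels go beyond that. The main setting adjusted each array by a single factor, but to a level common to both panels, and had been planned as an alternative. Cyclic loess and quantile normalization depart further, since they normalize the arrays of both panels together. No test between resistant and parental cells was run, no p-value is given for that comparison, and the test of microRNA lists was replaced by a description: the median difference of a list and its percentile among 10000 random lists of the same size matched on mean level in 5 bins. Lists with fewer than 3 detected members got no percentile. Lists and the rule for named microRNAs were fixed before the data were examined. Named were the microRNAs of the series title with miR-106a, which the published study names, the 10 with the largest mean difference in each direction among those with the same direction in every subline, and up to 4 detected members of each list with the largest differences. For each subline, the 2 microRNAs in each direction that lay farthest from the mean of the other sublines were added. Predicted small RNAs were counted and not named.

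Alternatives planned beforehand were no background correction, an offset of 50, cyclic loess, no detection filter, detection on every array, the authors' value table, and leaving out each subline in turn. Quantile normalization of the 5 arrays over the shared probes and centring of differences on the median probe were chosen after seeing the data. The alternatives without background correction and with another offset were run with the scaling of the main setting, 1 choice at a time. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Neighbouring microRNA genes were taken from the RefSeq gene table of assembly GRCh38.p14, used for neighbourhood alone.

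The procedure was tested on simulated data for the comparison of resistant with parental arrays over 556 shared probes. Among planted probes with a true signal of at least 200, the 2-fold rule recovered 19 of 19 with a log2 change of 2, 20 of 21 with a change of -2, 22 of 22 with a change of 3 and 18 of 18 with a change of -3. It took up 0 of 356 probes with no planted change, although the scaling moved the median of those by 0.38 on the log2 scale. The noise was set by hand rather than taken from these arrays, and no probe-by-probe difference between the panels was simulated. The 0 therefore does not say how often such panel differences meet the rule. The list percentile placed 10 of 200 random lists and 200 of 200 lists with a planted shift outside the central 95 percent. The planted shift was large, at 3 times the SD of the simulated values, and members varied independently. These counts therefore do not cover smaller shifts or lists whose members share a transcript.

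The number of arrays limits the precision. On the parental array a probe rested on a median of 39 beads, and the standard error over beads was 2.05% of the intensity in the median detected probe, which leaves out any difference between cultures or arrays.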

Results

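MicroRNA profiles were collected from 5 arrays, 1 of the parental ovarian carcinoma line SKOV3, which is sensitive to paclitaxel, and 4 of paclitaxel-resistant sublines derived from it. The sublines were read on version 2 of the panel with 1145 probes, of which 733, 767, 753 and 765 were detected in sublines 1 to 4 (64.0%, 67.0%, 65.8% and 66.8%). The parental line was read on version 1, and 353 of the 556 probes shared between the panels were detected (63.5%). On those shared probes 328, 356, 342 and 355 were detected in sublines 1 to 4. The median shared intensity was 135, 170, 156 and 171 in the sublines and 242.5 in the parental line. The brightest probe reached 40322, 41242, 42654 and 43973 in the sublines, while 3 parental probes stood at the scanner limit of 65535. Those belonged to let-7a, miR-21 and miR-24, which could not be told from one another, and their measured differences of -0.44 to -0.98 on the log2 scale over the sublines are bounds, since the parental level is saturated.

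The first comparison asked which microRNAs differ between resistant sublines and their parent, and since each group was read on its own panel, a difference between groups cannot be told apart from a difference between panels. Of the microRNAs in the series title, miR-591 (chromosome 7) was among the brightest on the parental array and near background in every subline. Its parental intensity was 65432, close to the scanner limit, and the sublines read 110, 114, 132 and 144, with detection p-values of 0.00104 to 0.0350. The measured log2 difference was -9.84 ± 0.19 (SD over 4 sublines, as for all differences here), and with a level near the limit on one side and near background on the other its size is not exact. No named probe bore the name miR-1061, which the title also gives. miR-106a (chromosome X, mature sequence AAAAGTGCTTACAGTGCAGGTAGC), a member of the miR-17 family, which is known to be driven by MYC, read 2127 in the parental line and 19354 to 24986 in the sublines. Its level was 11.1-fold higher, with a log2 difference of 3.48 ± 0.06 (4.23 after quantile normalization), and miR-20a, whose mature sequence lies within 2 bases of it, read 59899 in the parental line. Both microRNAs met the 2-fold rule under every scaling tried on the full set of shared probes, and miR-106a had no value in the authors' table used here.

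Of 379 shared probes detected in the parental line or in every subline, 35 were at least 2-fold higher and 95 at least 2-fold lower in every subline, together 34.3%. Among named microRNAs, 13 were higher and 52 lower out of 213. The split between directions moved with the scaling, and the median probe lay at -0.45 on the log2 scale in the main setting and at 0.07 after quantile normalization. The share of higher probes among those that met the rule was 26.9% in the main setting, 40.6% with cyclic loess (52 higher, 76 lower), 45.5% with differences centred on the median probe (56 and 67), 52.1% after quantile normalization (61 and 56) and 57.1% in the authors' value table (36 and 27). Under all of main scaling, loess, centring and quantile normalization, 35 probes were higher and 55 lower, among them 46 named microRNAs. By detection alone, 33 probes were detected in the parental line and in no subline, and 26 in every subline and not in the parental line. By rank within each array, 19 probes stood at least 25 percentile points higher and 22 at least 25 points lower in every subline.

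**Figure D1:**
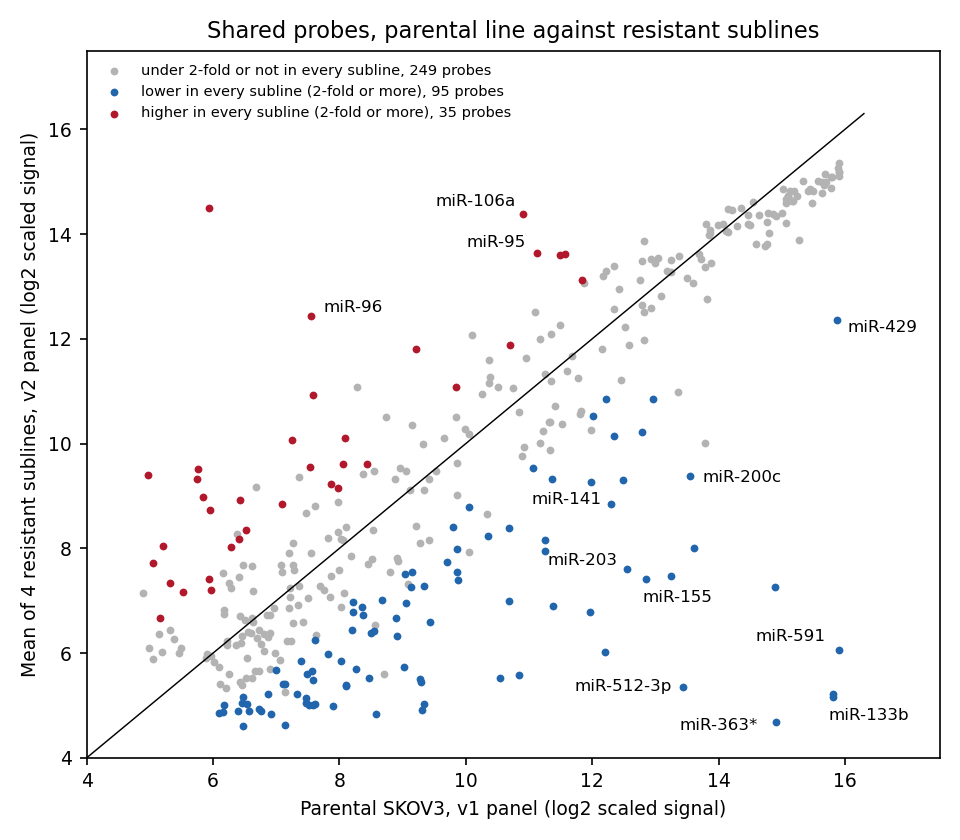
Log2 scaled signal of the 379 detected shared probes, parental line on the horizontal axis (version 1 panel, 1 array) against the mean of 4 resistant sublines on the vertical axis (version 2 panel), with the line of equal level. Red points mark the 35 probes higher and blue points the 95 probes lower in every subline by the 2-fold rule, and the brightest parental probes that lie near the bottom edge include miR-591, miR-133b and miR-363*.

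Besides miR-106a, the microRNAs that stood highest over the parent were led by miR-96, with a difference of 4.87 ± 0.09. miR-96 comes from the polycistron of miR-183, miR-96 and miR-182, but miR-183 (0.02 ± 0.11) and miR-182 (-0.06 ± 0.05) lay close to the parental level, and each had another sign in at least 1 alternative setting. miR-589 and miR-663 were not detected in the parental line and were detected in every subline, at mean levels at least 9.41-fold and at least 7.45-fold higher in the main setting, and at least 4.64-fold and 3.66-fold higher without background correction. The spread over the sublines was wide for miR-589 (SD of 1.56), which did not meet the rule without background correction. miR-95 (2.50 ± 0.25), miR-425 (2.11 ± 0.10), miR-378 (2.05 ± 0.21), miR-215 (2.02 ± 0.84) and miR-105 (2.02 ± 0.29) followed and met the rule under every scaling, although miR-215 did not without background correction, where its smallest subline difference was 0.80. miR-504 had a mean difference of 2.80 ± 2.20 and did not meet the rule.

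Of the microRNAs that stood lowest, miR-133b, known from striated muscle, miR-569 and miR-363* were bright in the parental line, with intensities of 61343, 61383 and 32774, and not detected in any subline. In the main setting the parental level was at least 1151-fold, at least 1152-fold and at least 614-fold above the mean of the sublines, and without background correction, which gave the lowest bounds, at least 476-fold, 476-fold and 254-fold. miR-363, from the hairpin of miR-363*, differed by 0.44 ± 0.59. miR-512-3p was likewise undetected in the sublines (at least 223-fold lower, and at least 92.6-fold without background correction), as was miR-583 (at least 29.9-fold, and at least 13.1-fold). The others were miR-512-5p (-6.18 ± 0.80, detected in 3 of 4 sublines), miR-624 (-5.77 ± 0.19), miR-155 (-5.45 ± 1.38) and miR-452* (-5.18 ± 0.11). All microRNAs of this paragraph except miR-363 met the rule under every scaling, and of those that met it miR-512-5p and miR-155 alone had a value in the authors' table.

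The miR-200 family, which represses the mesenchymal transcription factors ZEB1 and ZEB2 and marks epithelial cells, was lower in the sublines. All 5 members lay below the parental level in every subline, except miR-200b in subline 3 after quantile normalization and after centring on the median probe, and 3 met the 2-fold rule, under every scaling: miR-200c (-4.17 ± 0.60), miR-429 (-3.51 ± 0.65) and miR-141 (-3.45 ± 0.40). miR-200a differed by -1.38 ± 0.33 and miR-200b by -0.95 ± 0.42 and did not meet it. The median of the family was -3.45 and stood at percentile 0.07 of random lists matched on level, whose central 95 percent ran from -1.13 to 1.21. It was the 1 list outside that range in the main setting. Its members lie on chromosomes 1 and 12 alone, and miR-141 and miR-200a differ by 2 bases. Random lists draw microRNAs without such ties, and several lists were examined, so the percentile can be too extreme. miR-203 (-4.94 ± 1.02) and miR-205 (-1.88 ± 0.27), the microRNAs of squamous epithelium on the list, both met the rule, although miR-205 did not under every scaling.

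**Figure D2:**
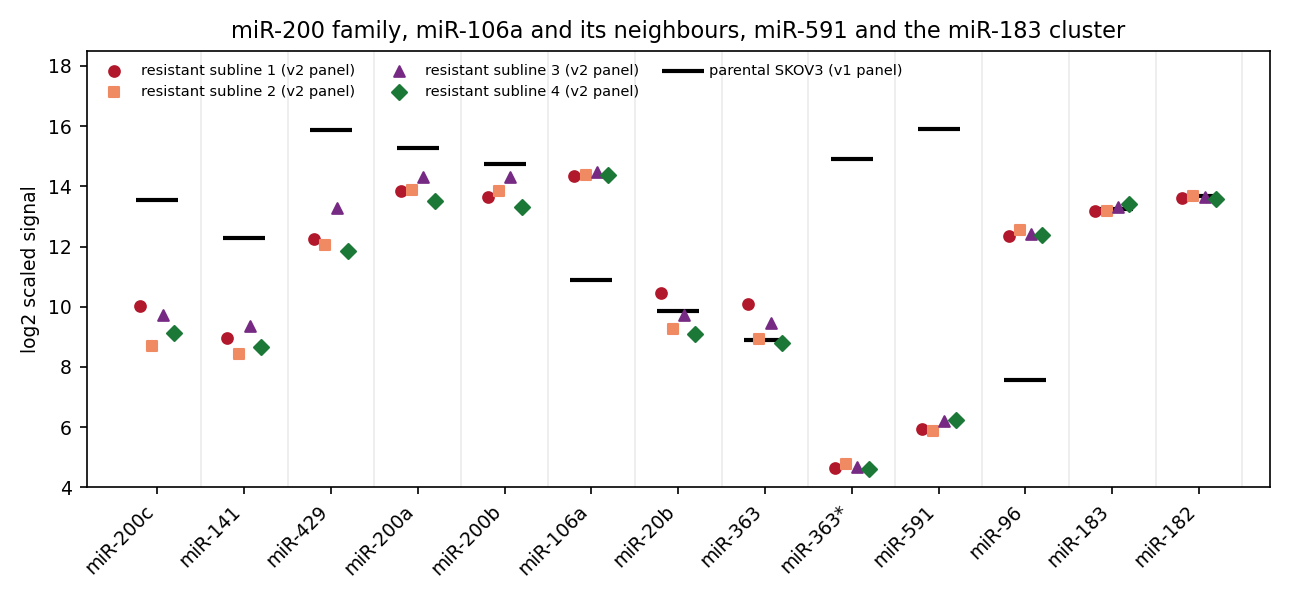
Log2 scaled signal of the miR-200 family, of miR-106a with its neighbours miR-20b, miR-363 and miR-363*, of miR-591 and of the polycistron of miR-183, with 1 marker per resistant subline (version 2 panel) and a black bar for the parental array (version 1 panel). In this scaling all miR-200 members lie below the parental bar, miR-106a and miR-96 lie above it, and miR-363* lies near 5 in the sublines while miR-363 from the same hairpin lies around the parental bar.

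Large microRNA clusters on chromosomes 19 and 14 also held low members. Of 9 detected microRNAs of the primate-specific chromosome 19 cluster, which is active in placenta, 5 met the rule and all of these were lower, under every scaling, with miR-519a at -3.17 ± 0.97 and miR-517a at -2.56 ± 0.23. The list median of -2.12 stood at percentile 6.12 of random lists. In the list for the imprinted cluster on chromosome 14, which counts miR-345 although its place in that cluster is uncertain, 10 of 10 detected members lay below the parent in every subline in the main setting, some of them with another sign under other scalings, 6 met the rule and 3 did under every scaling. miR-412 was detected in no subline and at least 12.6-fold lower, or at least 5.98-fold without background correction, miR-376a was detected in 1 of 4 sublines, at a measured difference of -2.70 ± 0.66, miR-433 differed by -2.06 ± 0.01 and miR-345 by -2.20 ± 0.74, the last not under every scaling. That list's median of -1.43 stood at percentile 63.0, so random lists of like level were as low. It was -0.88 after quantile normalization and -0.22 in the authors' value table, which holds fewer probes. miR-507, the 1 measured member of a testis cluster on chromosome X, differed by -4.48 ± 0.09.

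Among microRNAs that respond to p53, miR-34b was detected in no subline and at least 7.63-fold lower, or at least 3.93-fold without background correction, whereas miR-34a lay at 1.21 ± 1.19 and did not meet the rule. In the list of miR-192, miR-194 and miR-215, miR-215 alone met it, though not without background correction, while miR-192 lay at 0.21 ± 0.58 and miR-194 at -0.20 ± 0.48, the latter with another sign after centring. Of 10 detected members of the miR-17~92 cluster and its paralogs, miR-106a alone met the rule. miR-18a lay at -0.77 ± 0.23, miR-20a at -0.68 ± 0.08 and miR-106b at -0.48 ± 0.06, the last 2 with the opposite sign after quantile normalization, and the list median was -0.20 (percentile 82.0) and 0.28 after quantile normalization.

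No member met the rule in the abundant families, and in each of them at least 1 member changed sign with the scaling. The 8 detected members of the let-7 family, whose processing LIN28 blocks, had a median of -0.62 (percentile 7.50) and of 0.04 after quantile normalization, with miR-98 at -0.95 ± 0.10, let-7i at -0.91 ± 0.10, let-7b at -0.88 ± 0.12 and let-7g at -0.64 ± 0.12. The 7 members of the miR-15 and miR-16 family had a median of -0.59 (percentile 23.7) and of -0.01 after quantile normalization, with miR-497 at -0.99 ± 1.09, miR-15b at -0.84 ± 0.09, miR-16 at -0.75 ± 0.10 and miR-15a at -0.59 ± 0.10. The clusters of miR-23 and miR-27 had a median of -0.55 (percentile 31.5), and 0.21 after quantile normalization. The miR-30 list stood at -0.55 (percentile 36.4) and 0.12, the miR-181 list at -0.25 (percentile 57.3) and 0.07, and the miR-130 pair at -0.40 and -0.14. For the miR-29 list the medians were 0.14 (percentile 71.3) and 0.34. miR-221 lay at -0.36 ± 0.05, with the opposite sign after quantile normalization, and miR-222 at 0.34 ± 0.09. miR-210, the hypoxia marker, lay at 0.15 ± 0.08.

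The list of miR-99, miR-125 and miR-10 families had a median of -0.11 (percentile 79.8), 0.22 after quantile normalization, and no member that met the rule, with miR-10b at 1.04 ± 0.20 and miR-99a at -2.37 ± 2.02. The miR-148 list had a median of -0.34 (percentile 24.6), with the opposite sign after centring, and held miR-148b at 1.03 ± 0.10 and miR-152 at -3.77 ± 1.95, neither of which met it. miR-214 of the mesenchymal cluster lay at -1.78 ± 0.58 and miR-372 of the pluripotent cell clusters at 0.31 ± 0.37. Of 20 detected microRNAs that publications have tied to taxane or multidrug resistance, 1 was higher by the rule (miR-378) and 3 were lower (miR-200c, miR-155 and miR-203). The list median was -0.65 (percentile 3.79) and -0.09 after quantile normalization, where it lay outside the range of random lists (percentile 0.27), as it did in the authors' value table.

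No detected marker of other cell types met the rule as higher. Of 5 detected blood microRNAs 3 were lower by the rule, miR-155, miR-223 (-2.12 ± 0.63) and miR-142-3p (-2.10 ± 0.49), of which miR-155 alone did so under every scaling, and the list median of -2.10 stood at percentile 13.4. miR-143 (-1.96 ± 0.26) and miR-145 (-1.20 ± 0.18), known from fibroblasts and smooth muscle, lay below the parent, miR-143 by the rule but not under every scaling. The endothelial miR-126 lay at -0.30 ± 0.09, with the opposite sign after centring. The 3 detected neuronal microRNAs had a median of -0.53 (percentile 26.6), with miR-9 at -1.15 ± 0.91, miR-138 at 0.77 ± 0.62 and miR-137 at -0.53 ± 0.28. No probe was matched to the hepatocyte marker miR-122.

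No test was run for these differences, since a single parental array on another panel stood against 4 sublines. When each subline in turn stood in for the parent, the other 3 met the same rule at 6, 18, 7 and 17 probes, against 138, 138, 136 and 143 probes for the parental array and the same 3 sublines.

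The second comparison set each subline against the parent alone. At least 2-fold differences were found at 186, 201, 180 and 190 of the 379 detected shared probes in sublines 1 to 4. Between pairs of sublines 16 to 67 of these probes were 2-fold apart (4.22% to 17.7%). The SD of log2 differences over probes was 0.505 to 1.07 between sublines and 2.05 to 2.21 between a subline and the parent. Rank correlations across all 1145 probes, which are not independent replicates, were 0.982 between sublines 1 and 3, 0.972 between sublines 2 and 4, and 0.942 to 0.957 for the other pairs of sublines. Against the parent they were 0.808 to 0.833 over the 556 shared probes.

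Within the version 2 panel, where all sublines can be compared directly, 89 of 829 probes detected in at least 1 subline spanned 4-fold or more over the sublines (10.7%), 22 of them named microRNAs, while the median probe spanned 0.59 on the log2 scale. Each value below is a single array. miR-622 stood at log2 levels of 11.50 and 10.45 in sublines 2 and 4, whereas it was not detected in subline 1 and was near background in subline 3 and in the parent (5.83 and 6.38). miR-504 and miR-610 were likewise higher in sublines 2 and 4, with miR-504 at 13.29 and 12.64 in sublines 2 and 4 against 8.94 and 9.45 in sublines 1 and 3, and miR-610 at 12.60 and 11.96 against 8.11 and 9.37. miR-135a stood at 10.91, 8.74 and 11.22 in sublines 1 to 3 and near background in subline 4 (5.78), and miR-135b at 12.36, 10.45 and 11.17 against 8.24.

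Further microRNAs differed between the sublines as follows. miR-152 was at 12.90 in subline 1 and at 8.58 to 9.35 in the others, with the parent at 13.78. miR-99a was at 13.74 in subline 4 and at 8.88 to 10.83 in the others, with the parent at 13.36. miR-155, an oncogenic microRNA of lymphocytes, was at 9.46 in subline 1 and at 6.45 to 6.87 in the others, all below the parent at 12.86. miR-551a was at 11.45 and 11.65 in sublines 2 and 3, 8.78 in subline 1 and 9.75 in subline 4, with the parent at 11.33. miR-345 was lowest in subline 2, at 9.15, and highest in subline 4, at 10.78, with the parent at 12.34.

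**Figure D3:**
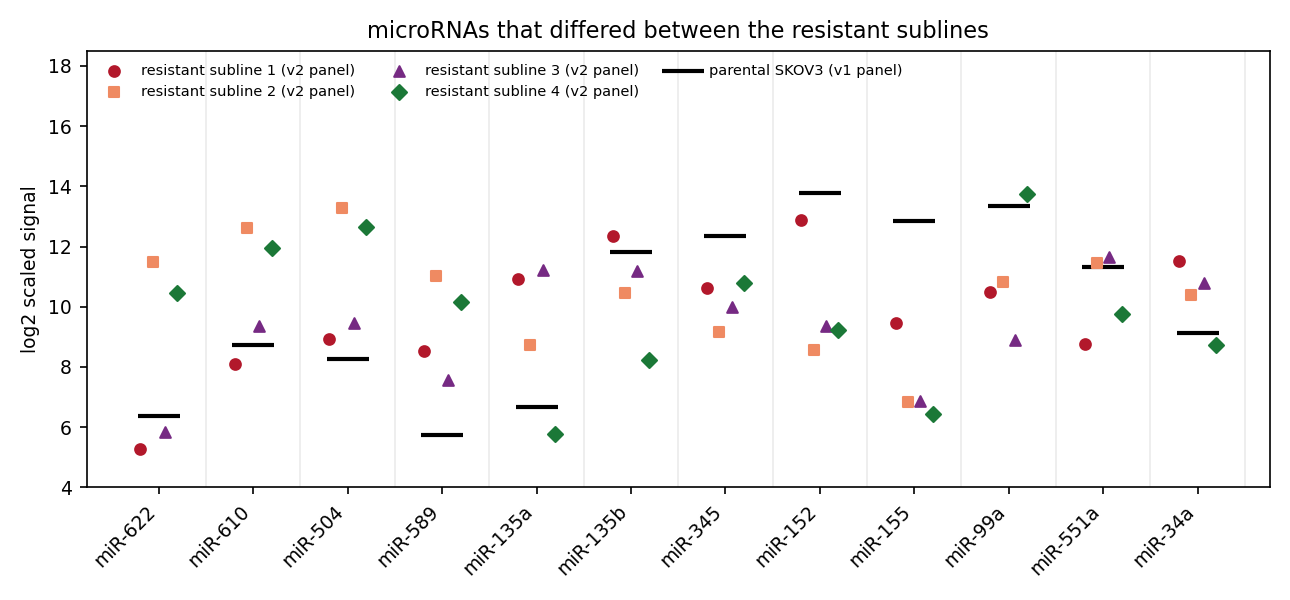
Log2 scaled signal of microRNAs that differed between the resistant sublines, with 1 marker per subline (version 2 panel) and a black bar for the parental array (version 1 panel). miR-622, miR-610 and miR-504 were higher in sublines 2 and 4, miR-135a spans from 5.78 in subline 4 to 11.22 in subline 3, and miR-152 in subline 1 and miR-99a in subline 4 lie near the parental bar.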

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

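The count after quantile normalization in the first pattern below, and in the second the repeat without miR-106a and the median of miR-363 and miR-20b, were chosen as tests after the result was seen, and the other tests of this part were set before their results were seen.

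In the first pattern, the parental array stood apart from the 4 sublines, with 130 of 379 probes meeting the 2-fold rule. A difference in scale or saturation between the panels is argued against as the whole cause, since 117 probes met the rule after quantile normalization, while 1 subline against the other 3 gave at most 16. Probe-by-probe differences between the panels stay open. Neighbouring microRNA genes were paired when within 10 kb of each other, of unlike sequence and with at least 1 of them changed. That rule did not leave out strands of one hairpin. The 39 pairs had a median gap in their differences of 1.91, against 2.25 for random partners. A share of 0.14 of random sets had a gap as small. That share neither excludes panel differences nor shows them, and resistance itself, as the design has it, stays open and untested because each panel holds 1 group alone.

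The second pattern was the higher level of miR-106a in the sublines. A candidate explanation is that the version 2 probe also reads close relatives that the version 1 probe leaves out: over 14 microRNAs with a relative within 2 bases and at least 4-fold brighter on the parental array, the median excess was 1.67 over others of like parental signal (permutation p = 0.0008, 1-sided), and 1.25 over 13 without miR-106a itself (permutation p = 0.0065). The excess was above 0 for 9 of the 14, such as miR-135a (3.17) and miR-215 (3.32). The differences behind both varied between sublines read on the same panel, with SDs of 2.51 and 0.84. It was below 0 for 5, with miR-519a at -2.39 and miR-141 at -2.23. The relative taken for miR-106a was miR-20a, at a parental intensity of 59899 against 2127. miR-20b, among the 9 with an excess above 0, had the same relative and a parental intensity of 1081. Its excess was 1.25, but its own difference was -0.24 ± 0.60 in the main setting. That excess thus came from lower values of the others, and miR-20b did not rise as miR-106a did. miR-17-5p, whose name the family bears, read 20531 on the parental array, and no subline value was matched to it. The test set beforehand for a rise of the transcript shared by miR-106a and miR-363 was undecided. Over all 3 measured neighbours within 10 kb, miR-363* among them, the median was -0.24, with an SD of 5.965 over the neighbours. The later test argues against a rise as large as the difference of miR-106a, as far as the probes of both panels read those neighbours alike. The neighbours detected on every array, miR-363 (0.44) and miR-20b (-0.24), had a median of 0.10 ± 0.59 against 3.48 (0.77 ± 0.66 against 4.23 after quantile normalization). A smaller rise of the transcript cannot be told apart from none within that spread, and a rise of mature miR-106a alone in resistant cells stays open, which the finding on relatives does not exclude.

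The third pattern was miR-363*, bright on the parental array and undetected in every subline. A fall of its precursor transcript is argued against only as far as the probes of both panels read miR-363 alike. miR-363, from the same hairpin, differed by 0.44 ± 0.59, and that SD over sublines holds no difference between panels. By contrast, miR-363* was at least 614-fold lower (at least 254-fold without background correction). A different probe design or a different target on the panels, and a change in which strand of the hairpin is kept, may each account for this pattern and stay open, as no value here decides between them. miR-591, miR-133b and miR-569 were likewise bright on the parental array and at or near background in the sublines. A different probe design or target stays open for them too and was not examined.

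Of 91 named microRNAs, 7 had 1 subline far from the other 3 by the gap between them, where chance alone gives 4.55 (about 1 in 20) in a set not chosen for it. Some of the 91, miR-155 among them, were named in part because a subline lay far from the others, and 6 of the remaining 81 had such a gap, against 4.05 by chance. miR-155 stood higher by 2.73 on the log2 scale in subline 1 than the mean of the others. The other gaps were small: miR-133b 0.26 in subline 3 and miR-569 0.18 in subline 2, both undetected in the sublines, miR-222 0.18 in subline 1, and in subline 4 miR-29c -0.16, miR-23b -0.17 and miR-27b -0.14.

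Some signal lay outside the comparisons. Of the 589 version 2 probes with no parental value, 376 were detected in all 4 sublines. Of the 111 rows of the version 1 table whose intensity equals no merged parental value, 104 were detected on the parental array, and 85 of the rows are microRNAs, among them miR-17-5p with an intensity of 20531.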

How the results depend on the processing

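Quantile normalization over the shared probes and centring on the median probe were chosen after seeing the data. The total of 130 probes that met the 2-fold rule stayed within 1.5 times under no background correction, an offset of 50, cyclic loess, quantile normalization and centring (92 to 128). It was 131 with no detection filter and 136 to 143 without each subline in turn. Those settings can only add probes to the 130 by construction, so they could not show a loss. The total was 63 of 327 compared probes in the authors' value table and 70 of 285 among probes detected on every array, against 130 of 379. The share fell in both, so the smaller number of probes does not account for the whole drop. The 35 higher probes became 20 without background correction, 61 after quantile normalization, 56 after centring and 22 among probes detected on every array. The 95 lower probes became 56 after quantile normalization, 27 in the authors' table and 48 among probes detected on every array. Quantile normalization and centring move the median probe from -0.45 towards 0 by construction, and the cause of the other changes was not tested. In sublines 1 to 4 the authors' table gave 103, 128, 102 and 110 of 327 probes 2-fold apart from the parent. Probes detected on every array gave 112, 127, 103 and 115 of 285. The main setting gave 186, 201, 180 and 190 of 379, a higher share in each subline. Quantile normalization and the authors' table each placed 2 lists outside the random range, the miR-200 family and the list tied to taxane resistance (percentiles 0.27 and 0.88), and the miR-200 family was outside in every setting run. Of 897 values of named microRNAs under alternatives, 651 moved by less than the SD over sublines and 246 by more. Values without 1 subline are among the 651 by construction, since leaving out 1 of 4 values cannot move their mean by that SD. The 651 therefore overstate how far the values held under other processing. A microRNA that met the rule was reversed in 0 of the values, although 21 of the 91 named microRNAs, none of which met it, had another sign in some setting. Of the 35 named microRNAs that met the rule, 2 did not without background correction (miR-215 and miR-589), 1 under cyclic loess and 1 after centring (miR-223 in both), 5 after quantile normalization, 4 of the 22 in the authors' table and 11 among probes detected on every array, all 11 through that filter itself. The limma test, its variance models and the set tests planned with it were not run, because the parental array is alone on its panel. No paired analysis was possible because the parental line has a single array and no number shared with the sublines. Signal over background limits the dim probes: the estimated background was 67.6, 76.3, 73.9 and 73.4 in sublines 1 to 4 and 100.9 in the parental line, and levels near it have no order.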

Other observations

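All tests in this part were chosen only after the result was seen. Within the version 2 panel, microRNAs of several genomic clusters differed between the sublines in the same way. miR-497 and miR-195, which share a transcript on chromosome 17, were both lowest in subline 4, miR-497 at a log2 level of 8.64 against 10.51 to 11.07 in the others and miR-195 at 11.42 against 12.86 to 13.15. The strands of the miR-9 hairpin moved together as well, with miR-9 at 11.08 and 11.17 in sublines 1 and 3 and at 9.93 and 9.29 in sublines 2 and 4, and miR-9* at 11.06 and 10.44 against 9.34 and 8.71. In the cluster of miR-424 and miR-503 on chromosome X, subline 3 held the highest and subline 4 the lowest level of miR-424 (14.33 and 13.99), miR-503 (12.82 and 11.81), miR-542-3p (11.40 and 10.41) and miR-542-5p (12.01 and 10.88). In the miR-200 cluster on chromosome 1, subline 3 was likewise highest for miR-429 (13.30), miR-200a (14.32) and miR-200a* (9.53), and subline 4 lowest (11.84, 13.52 and 7.71), whereas miR-200c and miR-141 on chromosome 12 were lowest in subline 2 (8.69 and 8.42) and highest in different sublines, miR-200c in subline 1 (10.01) and miR-141 in subline 3 (9.35). Other neighbours did not move together: miR-302b* was at 10.64 and 10.01 in sublines 2 and 4 and 6.79 and 7.27 in sublines 1 and 3, while miR-302a* lay at most 0.08 from its mean over the sublines. These examples were picked after their values were seen, and each level is a single array.

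A hypothesis drawn from this is that neighbouring microRNA genes vary together between the sublines, as clusters. Over 10 clusters of neighbouring genes with a member that spanned at least 2-fold, the median root-mean-square gap between subline profiles, each centred on its mean, was 0.324 on the log2 scale, against 0.804 for random partners. A share of 0.0005 of 2000 random partner sets had a gap as small, the smallest share they can give. Those neighbours include strands of one hairpin and microRNAs of near-identical sequence, which one probe could read together. A pair of the latter kind, miR-215 and miR-192, lies on chromosomes 1 and 11 and was joined through miR-194, which is annotated on both. With both kinds left out, the gap over 9 clusters was 0.310 against 0.802, and the share of random sets was again 0.0005. The tests suggest a shared source for part of these differences, but no array was repeated, so an effect of the culture or the extraction cannot be told apart from a lasting difference between sublines.

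miR-106a did not follow its neighbours within the same panel. miR-20b and miR-363 lay at 10.44 and 10.10 in subline 1 and at 9.10 and 8.81 in subline 4, while miR-106a spanned 0.13 on the log2 scale over the 4 sublines.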
